A study of Chlamydomonas reinhardtii with 4 samples.

How the data were processed

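Total RNA of Chlamydomonas reinhardtii strain 4A+ was compared on 4 spotted cDNA slides, each hybridised with RNA from rose bengal-treated and from mock-treated cells in the 2 dyes Cy3 and Cy5. Per the labels, slides 1 and 2 carried the RNA of biological replicate 1 and slides 3 and 4 that of biological replicate 2, with the dyes switched within each pair. Treated RNA was in Cy5 on slides 1 and 3 and in Cy3 on slides 2 and 4.

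The authors deposited 1 log ratio per spot, one dye over the other, here read as log2 values and centred near 0 before deposit. The log base is not given in the sources used here, so every fold change rests on that reading. Scanner, background correction, normalization and spot filter are likewise not given. The median of each deposited column lay within 0.01 of 0 (-0.01, 4e-04, -3e-04 and -6e-04 on slides 1 to 4), so the deposited values had been centred by some method. Slide 1 was given to 2 decimals, and the values of the others had more. The 11520 spots of a slide fell into 4 grids of 2880 positions. All 106 clones that the platform annotation names had 4 spots exactly 2880 apart, and the values of the grids correlated at 0.47 to 0.93 across positions, so the 4 spots of a position were treated as repeats of 1 clone.

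Which dye stands in the numerator is also not given. Before the data were examined, the rule was to read the columns as Cy5 over Cy3 and turn slides 2 and 4 if both dye-swap pairs correlated below 0, and to leave them if both correlated above 0. Over all 2597 positions r was -0.39 for slides 1 and 2 and 0.03 for slides 3 and 4, a case the rule did not cover. The rank correlations, -0.02 and 0.27, did not favour turning. Over the 61 positions with a size of 0.7 or more on some slide, r was -0.92 and -0.64, and without position 671 it was -0.9 and -0.52. The columns were therefore read as one fixed dye over the other, and slides 2 and 4 were turned, a choice made after these values were seen. If the columns had been turned to treated over untreated before deposit, the treatment and dye contrasts would change places, as would the replicate and slide-noise contrasts. The overall sign stays open. A positive value means higher in treated cells if the columns are Cy5 over Cy3, and lower if they are Cy3 over Cy5, and all signs turn together.

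Spots of a position were averaged per slide, a position needed a value on all 4 slides, and each slide was centred on its median position. Of 2880 positions, 145 had no value on any slide, 138 had values on some slides only, and 2597 were tested. The turned values of a dye-swap pair were averaged, since both slides carried the same 2 extracts, which left n = 2 biological replicates. The mean of the 2 replicates was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom per position, the test leaned on the variance shared between positions, to which limma gave 5.36 prior degrees of freedom. The number of arrays limits the precision.

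The test was checked on simulated data with 2597 positions, the prior spread of the real ones and their dye contrast, in 50 runs. The changed positions were spread evenly over sizes of 0.25, 0.5, 1 and 2 on the log2 scale. With 200 changed positions, it recovered 46.6% of changes of 0.25, 98.1% of 0.5 and 99.9% of 1 on the log2 scale, and 8.2% of its calls were false. With 40 changed positions the shares were 17.2%, 87.8% and 99.8%, and 17% of calls were false. In the same runs, a fit of the 4 slides as separate samples with a dye term had lower shares of false calls. These were 7.8% with 200 changed positions and 9.8% with 40. These shares depend on the mix of sizes. Only 2 of the real clones differed by 2-fold or more with one sign in both replicates, so the shares need not hold for the real data. With no changed position, 11 of 50 runs made at least 1 call. The adjusted p-values of this design were therefore too small, more so with 40 changed positions than with 200.

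Genes were named through the platform annotation given here, updated by gene identifier against the RefSeq table of assembly v5.5. It named 1 gene for 105 clones and several for 1 clone, and left 2774 positions without a name. All 100 different genes of the 105 clones matched the RefSeq table, which lists them by locus tag with no gene symbol. The build behind the annotation is not stated, so no coordinates are given. The 28 gene lists fixed before the data were examined, among them antioxidant enzymes, heat shock proteins and light-harvesting proteins, matched 0 clones, since both tables lack symbols and descriptions. Their set tests and the genes fixed by symbol were therefore not run. Genes named in the text are, in each direction, up to 10 annotated genes of the same sign on all 4 slides, those past the threshold first and then by size of mean change. For positions with no gene named, 2 each way are given by print position. All columns of the table were used.

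Alternatives covered the centring, the summary of spots, the filter on missing spots, scaling between slides, the 4 slides as separate samples with a dye term, the biological replicate as a block, each slide or replicate left out, and the variance model. For the block, limma returned no correlation with 4 slides and 2 terms, so a pooled estimate of 0.211 from the replicate and slide-noise contrasts was used.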

Results

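The slides measured how transcript levels differed between cells of the wild-type strain 4A+ given rose bengal and cells given water. Rose bengal is a photosensitising dye that produces singlet oxygen in light, and the labels give the search for singlet oxygen-regulated genes as the purpose. Cultures of 100 mL were grown in light of 50 µmol photons per m2 per s without an organic carbon source, and RNA was harvested 2 h after addition of 2 µM rose bengal. There were 2 biological replicates, each hybridised on 2 slides with the dyes switched. Of 11520 spots, 10649 and 10627 had a value on slides 1 and 2 (replicate 1), and 9533 and 9382 on slides 3 and 4 (replicate 2). The median SD between the spots of a clone was 0.136, 0.043, 0.092 and 0.109 on slides 1 to 4, on the log2 scale. Signs below are those of treated over untreated if the deposited columns are Cy5 over Cy3. The sources used here do not settle the dye order, and under the other order every sign turns. They do not settle either whether the columns are one fixed dye over the other, as read here. If the columns had been turned to treated over untreated before deposit, the treatment and dye contrasts below would change places, and 0 of 2597 clones would pass limma's test for treatment (568 with an unadjusted p under 0.05).

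Among the 2597 clones with a value on all 4 slides, the largest mean difference between treated and untreated cells was that of a single clone. The clone at print position 671, which has no gene named in the annotation used here, had a mean log2 ratio of -2.78 ± 0.11 (SD, n = 2), a 6.87-fold difference, with an adjusted p of 9.88e-06 in limma. It read -2.96, -2.75, -3.05 and -2.36 on slides 1 to 4 after turning, and its 14 measured spots had sizes of 2.33 to 3.27. The next clones on the negative side were much closer to 0. Among the clones with no gene named, position 641 had the second most negative mean of those that passed, at -0.85 ± 0.31 (SD, n = 2; adjusted p = 0.0409, limma). On the positive side, position 2866 reached 0.96 ± 0.32 (SD, n = 2; adjusted p = 0.0409, limma), and position 727 reached 0.81 ± 0.05 (SD, n = 2; adjusted p = 0.00629, limma). Position 727 read 0.93, 0.61, 1.21 and 0.48 on slides 1 to 4, a spread by dye order that its SD leaves out. With robust variance moderation, positions 2866 and 641 no longer passed (limma adjusted p of 0.0638 and 0.071), at the same means. Only positions 671 and 971 differed by at least 2-fold with one sign in both replicates. Position 971, named here after its value was seen, had the largest positive mean, 1.54 ± 0.84 (SD, n = 2). Its replicates read 2.13 and 0.94, and it did not pass the test (adjusted p = 0.0551, limma). This depended on the model: limma's adjusted p was 0.0174 with the biological replicate as a block and 0.626 with robust moderation.

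In all, 21 of 2597 clones passed limma's test at an adjusted p of 0.05, with 12 on the positive and 9 on the negative side. Of these 21, 19 had one sign on all 4 slides. A further 19 clones had an adjusted p of 0.05 to 0.1, and 297 an unadjusted p under 0.05. At a minimum of 1.5-fold with one sign in both replicates there were 19 clones, 11 positive and 8 negative. The count of 21 lay close to the threshold, since 19 of the 21 had adjusted p-values between 0.04 and 0.05. In the simulation with 40 changed positions, 17% of calls at this threshold were false, so some of the 21 may be false too. The count fell to 10 with robust variance moderation, and to 5 when slide 1 was left out of the mean of replicate 1. Replicate 1 is then slide 2 alone, in which the dye contrast does not cancel. When print blocks and columns were centred, the count fell to 1 (position 671). It was 47 with the median of spots and 91 with slides scaled to equal spread. The fall to 1 came with fewer prior degrees of freedom (2.65 against 5.36), not with smaller changes: after the print was centred, position 727 was at 0.82 ± 0.08, position 2866 at 0.94 ± 0.3 and position 641 at -0.84 ± 0.3 (SD, n = 2 each). The prior SD also fell, from 0.085 to 0.065. With the 5.36 prior degrees of freedom kept beside the lower prior SD, 59 clones passed, all 21 among them. That mix belongs to neither fit, so the 59 do not show that the 21 hold after centring.

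**Figure D1:**
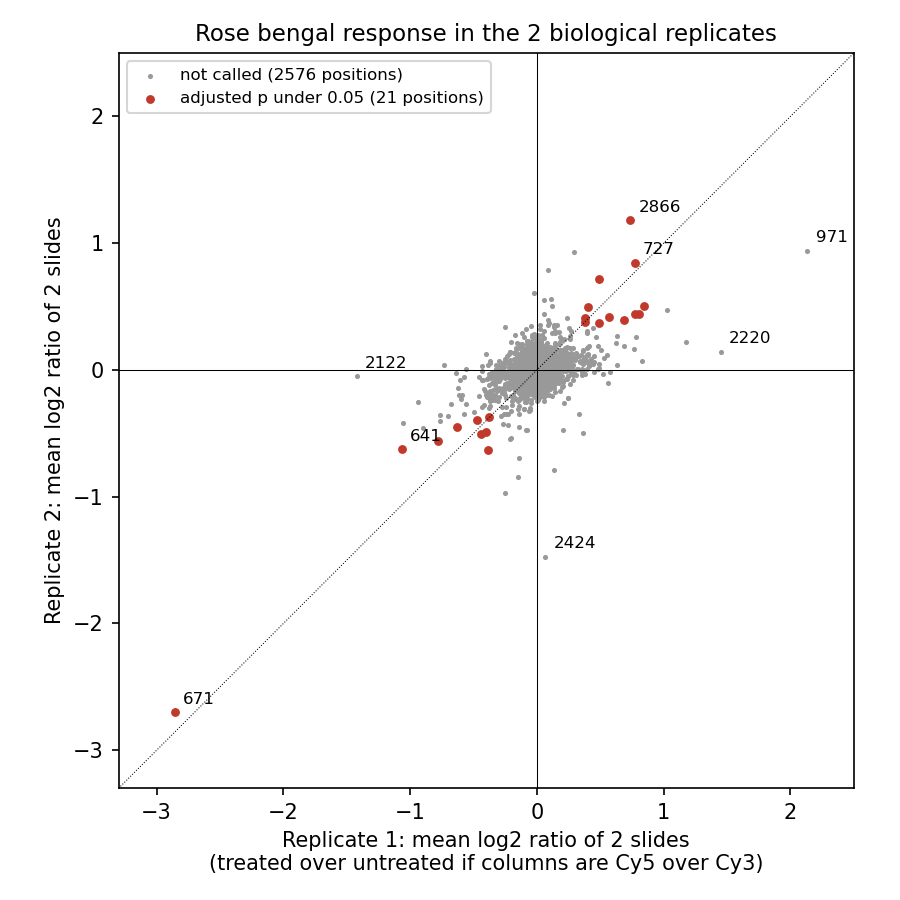
Mean log2 ratio of each of 2597 clones in biological replicate 1 (x axis) against replicate 2 (y axis), each the mean of 2 dye-swapped slides, with the 21 clones of adjusted p under 0.05 in red and the dotted line marking equal values. Position 671 lies near -2.86 and -2.7, far from all other clones, while positions 2122, 2220 and 2424 lie far from 0 in 1 replicate and much closer to it in the other.

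Among the annotated genes, mean changes were at most 0.68 in size on the log2 scale. Of 103 tested clones for 99 genes, 1 passed over all clones tested, CHLRE_16g680230v5, at -0.37 ± 0.01 (SD, n = 2; adjusted p = 0.0498, limma). It read -0.54, -0.21, -0.54 and -0.2 on slides 1 to 4, a spread by dye order that this SD leaves out. The largest mean among the annotated clones was that of CHLRE_09g391900v5, at -0.68 ± 0.31 (SD, n = 2), a 1.6-fold difference. It missed the threshold (adjusted p = 0.052, limma) although all 4 slides read between -0.92 and -0.41. CHLRE_06g272900v5 had a mean of -0.46 ± 0.16 and CHLRE_13g583550v5 one of -0.36 ± 0.09 (SD, n = 2 each; adjusted p = 0.052 and 0.0687, limma). The positive gene of largest mean, CHLRE_12g483700v5, was at 0.34 ± 0.07 (SD, n = 2; adjusted p = 0.0687, limma). On slides 1 to 4 it read 0.5, 0.28, 0.56 and 0.03, and CHLRE_06g272900v5 read -0.8, -0.35, -0.68 and -0.02. Both were near 0 on slide 4, and their SDs leave out this spread by dye order. When the p-values were adjusted over the list alone, that is over the 103 annotated clones, these 5 genes passed, 4 negative and 1 positive (limma adjusted p of 0.0176 to 0.018). That adjustment was added after the data were seen. With the biological replicate as a block, CHLRE_16g680230v5, CHLRE_09g391900v5 and CHLRE_06g272900v5 passed over all clones (limma adjusted p of 0.0212, 0.0174 and 0.0232). CHLRE_13g583550v5 and CHLRE_12g483700v5 did not (limma adjusted p of 0.0798 and 0.0763). The 5 passed neither over all clones after print blocks and columns were centred, nor with robust moderation, nor when slide 1 was left out of the mean of replicate 1. Centring the print hardly moved their means, which were then -0.38 ± 0.05, -0.66 ± 0.31, -0.47 ± 0.08, -0.38 ± 0.02 and 0.34 ± 0.06 in the order given (SD, n = 2 each), and robust moderation does not alter means. Without slide 1 in the mean of replicate 1 they were -0.29, -0.69, -0.35, -0.32 and 0.29. Replicate 1 is then slide 2 alone, so these means also carry part of the dye contrast.

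The other annotated genes of one sign on all 4 slides did not pass either adjustment. On the negative side, CHLRE_11g467569v5 had a mean of -0.27 ± 0.13 and CHLRE_07g346050v5 one of -0.23 ± 0.17 (SD, n = 2 each; limma adjusted p of 0.17 and 0.298). A further 4 had means between -0.13 and -0.1, namely CHLRE_09g395950v5, CHLRE_06g267200v5, CHLRE_16g673109v5 and CHLRE_02g085450v5, with limma adjusted p-values of 0.46 to 0.705. On the positive side, CHLRE_11g468450v5 had a mean of 0.33 ± 0.31, CHLRE_01g066552v5 of 0.22 ± 0.2 and CHLRE_16g671350v5 of 0.08 ± 0.02 (SD, n = 2 each; limma adjusted p of 0.279, 0.337 and 0.754). Some of these means came mostly from replicate 1. Replicates 1 and 2 read 0.55 and 0.12 for CHLRE_11g468450v5, 0.36 and 0.08 for CHLRE_01g066552v5, and -0.35 and -0.11 for CHLRE_07g346050v5. They read -0.19 and -0.01 for CHLRE_16g673109v5 and -0.36 and -0.18 for CHLRE_11g467569v5, and lay closer together for the other genes here. With 1 slide left out, the dye term gives the remaining slides unequal weight, so the shifts below come partly from that. In the 4-slide fit without slide 2, CHLRE_11g468450v5 fell to 0.16 and CHLRE_01g066552v5 to 0.1, while without slide 4 they rose to 0.5 and 0.35. CHLRE_07g346050v5 was at -0.12 without slide 1 and -0.34 without slide 3. Among the smaller means, CHLRE_16g673109v5 was at -0.04 without slide 1 and -0.16 without slide 3, CHLRE_02g085450v5 at -0.06 without slide 2, and CHLRE_16g671350v5 at 0.05 without slide 3. Only 4 annotated genes were positive on all 4 slides, so the positive side holds fewer than 10 names. In total, 15 of the 103 annotated clones and 357 of all 2597 (13.7%) had one sign on all 4 slides. Independent random signs would give a share of similar size, so one sign on all 4 slides does not by itself show a response.

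Where a gene was spotted as several clones, most of these lay near 0. The median-based SD of the treatment contrast over all clones was 0.07, so this does not show agreement between clones of a gene. The 3 clones of CHLRE_06g259900v5 had means of 0.01, -0.03 and -0.02, and the 2 of CHLRE_03g199800v5 had -0.03 and -0.07. For CHLRE_01g010000v5 the means were 0.14 ± 0.15 and -0.01 ± 0.01 (SD, n = 2 each), of opposite sign. None of these passed (lowest limma adjusted p = 0.553).

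**Figure D2:**
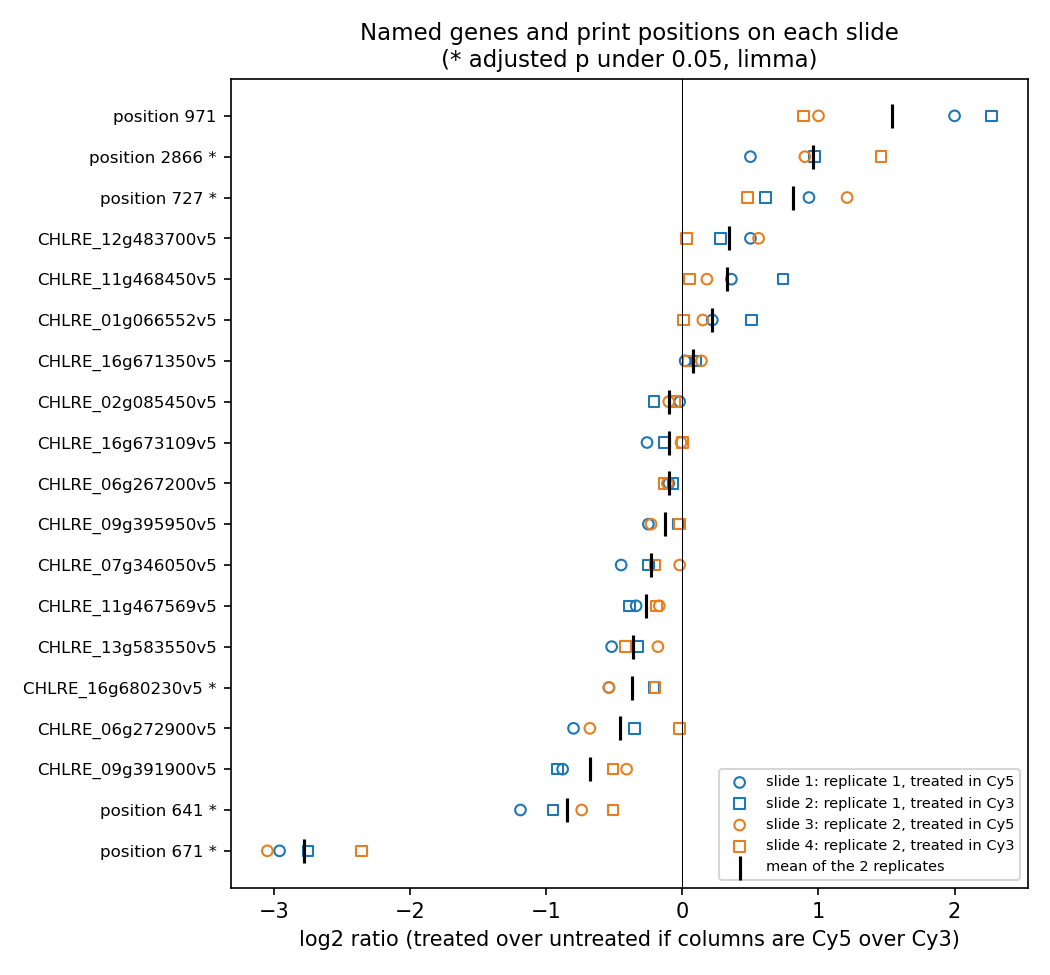
Log2 ratio (x axis) of each named gene or print position (y axis) on each of the 4 slides after turning, with colours for the biological replicates, shapes for the dye order and a bar at the mean of the 2 replicates. Every named item has one sign on all 4 slides, and position 671 at -2.78 stands apart from the annotated genes, which lie between -0.68 and 0.34.

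The 2 biological replicates gave partly the same values. Across the 2597 clones, their treated-over-untreated means correlated with r = 0.48 (95% bootstrap interval over clones 0.37 to 0.6). Without the 2 clones farthest from the median of replicate 1, r was 0.4, and without the clones that passed the test it was 0.34. The dye contrast, the mean without turning, correlated between replicates with r = 0.5. A correlation of this size therefore does not by itself show a response to the treatment. The rank correlation of the treated-over-untreated means was 0.25, lower than their r. These are correlations across clones, which are not independent replicates. In the bulk of the clones the treatment contrast was little wider than the noise: its median-based SD was 0.07, against 0.064 for the difference between replicates and 0.06 for slide noise. In the tails, 85 clones reached 0.3 or more, against 20 for the difference between replicates and 1 for slide noise. The low count for slide noise is no independent comparison, since slides 2 and 4 were turned because the largest values then agreed within pairs.

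The dye switch gives a treatment and a dye contrast from the same slides. The dye contrast, the mean of the 4 slides without turning, had a median-based SD of 0.104, larger than the 0.07 of the treatment contrast. The full SD, which weighs the tails, was 0.114 for dye and 0.137 for treatment, 33 and 85 clones reached 0.3, and 0 and 20 reached 1.5-fold. The turning was chosen from the largest values and places them in the treatment contrast, so these tail values do not compare treatment with dye. The dye contrast correlated between replicates with r = 0.5 across clones. No clone passed limma's test for a dye term at an adjusted p of 0.05 (0 of 2597), while 537 had an unadjusted p under 0.05. The same count was 0 when the dye contrasts of the 2 replicates were tested as 2 values (568 with an unadjusted p under 0.05). The dye contrast changed along the print: by column of 18 positions it ran from -0.069 in column 6 to 0.064 in column 15, while the treatment contrast lay between -0.036 and 0.022.

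**Figure D3:**
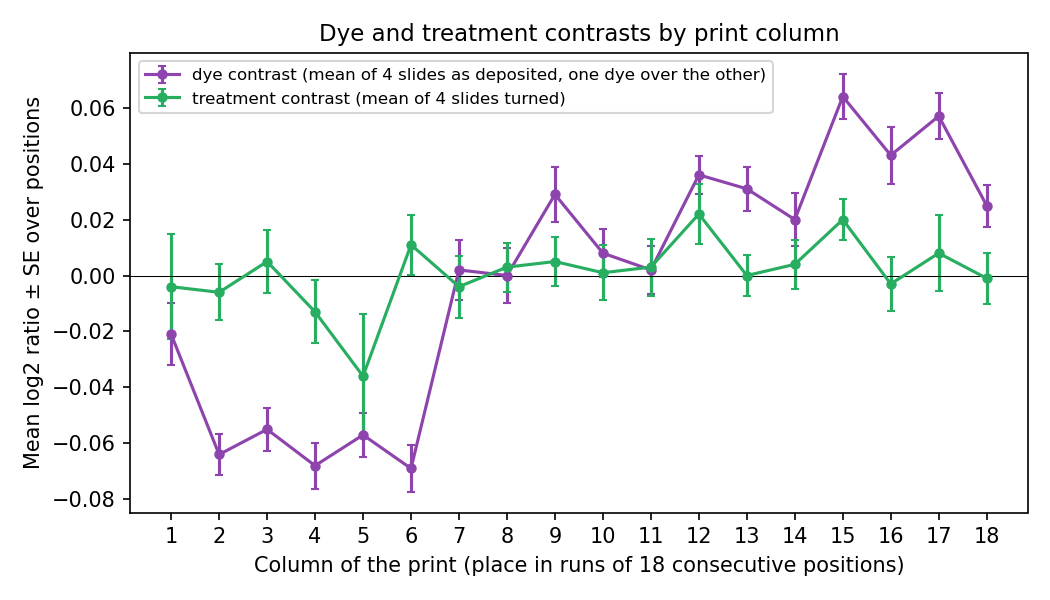
Mean dye contrast (purple) and treatment contrast (green) in log2 units (y axis) by column of the print (x axis, place within runs of 18 consecutive positions), with bars for the SE over 44 to 157 clones a column. The dye contrast lies below 0 in columns 1 to 6 and above 0 from column 12 on, and the treatment contrast shows no such run.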

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

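Alternatives named for the print layout and for slide 1 in the mean of replicate 1 were chosen after seeing the data. So were those for the orientation of the columns and the adjustment over annotated clones. The others were fixed before. Without slide 1 in its mean, replicate 1 is slide 2 alone, in which the dye contrast does not cancel. With the columns read as already treated over untreated, 0 clones were called by limma (568 with an unadjusted p under 0.05), 0 of them annotated, and 0 reached 2-fold. Against 21 called clones, the counts were 47 with the median of spots, 1 with at least 3 spots on every slide (position 727, as 671 has only 2 spots on a slide), 91 with slides scaled to equal spread, 45 with the 4 slides as separate samples, 10 with robust moderation, 0 with no moderation of the variance, 40 at an adjusted p under 0.1, 1 with print blocks and columns centred (59, with all 21 among them, if the prior degrees of freedom were kept) and 5 without slide 1 in the mean of replicate 1. Unadjusted p-values under 0.05 numbered 222 with 3 spots and 276 with the print centred. The 4-slide fit gave 106, 63, 178 and 145 without slide 1, 2, 3 and 4. There limma set the prior degrees of freedom to infinity, which treats the variance as known, against 5.36 in the reported fit, 10.53 with scaling and 2.65 with the print centred. With the replicate block the count was 27, of which 18 were among the 21, and without centring it was also 27. The split of 12 positive to 9 negative became 34 to 57 with scaling, 16 to 29 with the 4 slides, 12 to 15 with the block and 4 to 6 with robust moderation. Annotated clones called, 1 as reported, were 3 without centring, 3 with a value on 1 slide of each replicate, 3 with the replicate block, 4 with the median of spots, 5 with the 4 slides, 5 at a threshold of 0.1, 5 adjusted over the annotated clones alone, 5 with the print centred and the prior degrees of freedom kept, 6 with scaling, and 4 to 11 without 1 slide. They were 0 with 3 spots, robust moderation, no moderation, the print centred, or slide 1 left out of the mean of replicate 1. Clones at 2-fold or more, 2 as reported, were 1 with at least 3 spots and 19 at 1.5-fold, and 3 to 8 with 1 replicate alone. The replicate correlation of 0.48 was 0.25 by rank. Beyond these shown reasons the cause was not tested. With slides 2 and 4 turned, none of the 339 alternative values of the 19 named items changed sign. This is no test of their direction: all 19 had one sign on all 4 slides. Any fit that averages these same slide values, also with a slide or replicate left out, must keep that sign. Of the 339 values, 15 lost and 50 gained significance. Position 671 passed in 14 of 15 of these tests and position 727 in 14 of 16. The tests and the gains include 4-slide fits that count the 2 slides of a dye-swap pair as separate samples. Those without 1 slide also treat the variance as known. The tallies are therefore no measure of support, with n = 2 biological replicates. The set tests of the fixed lists were not run, as no clone matched. Missing spots limited slides 3 and 4 more (82.8% and 81.4% with a value) than slides 1 and 2 (92.4% and 92.2%).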

Other observations

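Apart from limma's test over both replicates, all tests in this part were chosen after the results were seen. Some clones had large values on both dye orders in 1 biological replicate and much smaller values in the other. Position 2424 read -1.81 and -1.14 on the slides of replicate 2, against -0.1 and 0.23 in replicate 1. Position 2122 read -1.58 and -1.26 in replicate 1, against 0.09 and -0.19 in replicate 2, and position 2220 read 1.34 and 1.56 in replicate 1, against -0.13 and 0.42. None passed the test over both replicates (limma adjusted p of 0.322 to 0.474), and none has a gene named here.

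Noise between the slides of a pair stays open as part of these differences. In the replicate contrast 20 clones reached 0.3 or more, against 1 in the slide-noise contrast, but these 2 contrasts change places if the columns were turned before deposit, which no source settles. A place in the print that was uneven by block or column is argued against as the whole source: of the 20 clones, 16 stayed at 0.3 or more once blocks and columns were removed, with a median of 0.94 of their size. Unevenness of another shape was not tested. That the replicate cultures differed in state or in their response, and uneven extraction of the RNA, stay open and were not tested.

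Position 671 is the clone most worth identifying. A preference of the clone for one dye stays open. Its dye contrast of 0.22 was 0.08 of its treatment contrast of 2.78 in size, but the ratio turns over if the columns were already treated over untreated at deposit, which no source settles. A mark at one place on a slide is argued against by the 14 measured spots in different grids, whose lowest size was 2.33. Cross-hybridisation to related transcripts could not be examined without the clone's sequence. The treatment remains an open explanation, with n = 2 cultures.

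The dye contrast followed the place in the print. Columns of 18 positions held 14.8% of its variance, above the highest of 100 shuffles of the positions (1.6%), and 0.8% of the variance of the treatment contrast. With the columns read as one fixed dye over the other, dye imbalance by column left in the deposited values may account for this part of the dye contrast. The correlation between clones 18 positions apart was 0.42 for the dye contrast and 0.05 for the treatment contrast. Clones of related content printed in the same columns cannot be excluded as another source, since 2774 positions have no name here.

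Of the 138 positions with values on some slides only, 7 reached a size of 1 or more on a slide, the largest at 2.86, and they were outside the reported test.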
